A study of Mus musculus with 300 samples.

How the data were processed

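The data are C1 single-cell RNA-seq values from 300 adult mouse spermatogonia that carried an ID4-EGFP reporter, in which EGFP brightness follows the Id4 locus. Per the labels' protocols, testes were dissociated enzymatically, enriched on Percoll and sorted for bright CD9 and EGFP, and the sorted cells were captured on Fluidigm C1 chips. Capture sites that held dead cells, debris or more than 1 cell were excluded by imaging, and cDNA was made with a SMARTer kit, which does not mark strand. Each cell's EGFP epifluorescence was measured on the chip, and the labels put it in a brightness quartile from Q1, the brightest, to Q4, the dimmest. The titles carry a number from 1 to 4, which was taken as the replicate preparation, each from several mice, since the labels name 4 such preparations. These hold 67, 82, 71 and 80 cells, and both the n of 4 and the pairing rest on this reading. A preparation and quartile together hold 15 to 22 cells. The preparation was taken as the replicate, so n = 4, and cells were not counted as replicates in the comparisons of quartiles. Only the random reassignments and draws of cells in the closing sections take the single cell as their unit, within preparations.

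The deposited table holds FPKM values (fragments scaled to transcript length and library size) for 23354 gene names and 300 cells. Its header names no unit, and FPKM is taken from Cufflinks, which the submitters' processing notes name together with TopHat, FastQC and Picard for builds mm10 and GRCm38, without versions. Per the deposited values, a cell's FPKM sum ran from 348305 to 682985, 5602 gene names stood at 0 in every cell, and 0 columns lacked a sample. No 2 columns were identical. Of the gene names, 140 matched no current or older symbol, among them 25 that a spreadsheet had turned into dates, and the latter are not named in the results. Id4 itself and the genes of the mitochondrial genome are not analysed here. A row called Id4e matches no gene symbol, and what it covers is not stated in the sources used here, so its values are given under that name only. If it holds transcripts of Id4 or of the reporter, its rise with brightness would follow from how the quartiles were made. Raw counts were not used here, so no count model was applied. An FPKM of 0 in a cell says only that the gene is listed at 0 there.

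For each gene the mean over cells of log2(FPKM + 1) was taken per preparation and quartile, which gave 16 means. Genes with at least 1 FPKM in at least 30 cells entered the tests, 10411 in all. limma 3.58.1 in R 4.3.3 was fitted to the 16 means with the quartile and, as a block, the preparation, with moderated variances that follow mean expression and are robust to outlying genes. All 16 means shared one estimate of spread. The block was part of the main design because quartiles were taken to be set within preparations. This was inferred from the nearly equal numbers of cells per quartile in each preparation. Adjusted p-values are Benjamini-Hochberg values over the 10411 genes, with a threshold of 0.05. The comparisons were the 6 pairs of quartiles and a trend with a step of 1 from each quartile to the next brighter one. A difference on the log2(FPKM + 1) scale understates the change of a gene with low values. SE is the standard error from limma, and SD is the spread over the 4 preparations.

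Same-numbered quartile means come from the same animals and the same chip, which is where the pairing comes from. Their deviations from the quartile means correlated at 0.0112 to 0.360 across genes (median 0.129). The median between preparations was -0.136, but subtracting the quartile means itself pushes that value below 0. Set against the means of other quartiles, 14 of 16 means correlated best with a mean of their own preparation.

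The 25 gene lists and a panel of 20 genes were written down before the data were examined. Lists with at least 3 tested members were compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over lists, with camera using an estimated correlation and fry beside it. Genes named in the text were chosen by a rule also fixed beforehand. It takes the panel and, for Q1 against Q4, the 10 largest differences in each direction past the threshold with one sign in all 4 preparations. It adds 5 more per direction for the trend, 3 per direction for each other pair, and up to 4 members per list by smallest p. Predicted genes and names with clone or accession codes were skipped.

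Shares of cells with at least 1 FPKM, the classes of cells by Gfra1 and Kit, and genes detected per cell were tested by an exact two-sided permutation of the quartile labels within preparations (331776 relabelings, smallest possible p 6.03e-06) on the mean slope over quartiles. A sign-flip test of Q1 against Q4 alone cannot go below p = 0.125 with 4 preparations. A cell was counted under another cell type when at least 3 and at least 50% of the measured members of that type's list stood at 5 FPKM or more.

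No read totals were used, but the low values keep the depth. A low gene's FPKM is a multiple of what 1 fragment is worth, so ratios of low values (under 3 FPKM) between 2 cells pile up at the ratio of their depths. The commonest ratio, within 0.03 on the log2 scale, held 17.6% of the low genes of a cell pair, and 97.9% of 15 reference cells' estimates lay within 0.05 of the cell's median on the log2 scale. Relative depth ran from 0.362 to 2.01 around a median of 1. Absolute depth is unknown, so no counting intervals are given for single genes. A share of 0 of 300 cells allows up to 1% (3 of 300 cells), which covers counting error only.

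The model was tested on the real cells, with quartile labels shuffled within preparations and 200 genes multiplied by known folds. A cell at 0 stayed at 0, so changes in the share of cells that hold a gene were not planted. For Q1 against Q4 the model called 8% of genes changed 2-fold, 28% of those changed 4-fold, 34% at 8-fold and 54% at 16-fold, and 2 of 10211 unchanged genes. For the trend it called 12%, 30%, 34% and 56%, and 4 unchanged genes. The permutation test gave p at or under 0.05 in 6.5% of 200 simulated unchanged tables and in 100% of 200 with a planted slope. The planted slope was large against the noise, so the 100% says nothing about weaker slopes.

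Alternatives were a pseudocount of 0.1, no filter, a filter of 150 cells, the log2 of the mean FPKM, cells rescaled to a sum of 1000000, no preparation block, a fit of the compared quartiles only, genes detected as a covariate, other detection thresholds, cells with markers of other types left out, and each preparation left out in turn. Centring each mean on its median gene was added after the data were seen. Gene positions are from GENCODE vM21 on GRCm38. Beyond the partners given in the results, exons of Neurog3 overlap Fam241b on the opposite strand, those of Sycp3 overlap Chpt1, those of Dusp1 overlap Ergic1 and those of Ndufa2 overlap Tmco6. Exons of Nanos2, Eomes, Sall4, Cd9, Rasgrp2, Uchl1, Ccnd2, Zfp36, Mcam and Tspan8 overlap noncoding or predicted genes there, and those of Pkm overlap one on the same strand. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.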

Results

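Single-cell transcriptomes of 300 ID4-EGFP spermatogonia from adult mouse testes were compared across EGFP brightness quartiles in 4 replicate preparations. ID4 is a transcriptional regulator enriched in spermatogonial stem cells, so the comparison asks how expression differs from the brightest to the dimmest cells of the reporter-positive pool. The quartiles held 79 cells in Q1, 78 in Q2, 71 in Q3 and 72 in Q4. On average 5541 genes stood at 1 FPKM or more in a cell, with a range from 2934 to 7817. Preparation 1 held fewer genes per cell, 4368 on average, than preparations 2, 3 and 4 with 5813, 5572 and 6216. Genes per cell were slightly higher in brighter cells, 5687 ± 697 in Q1 and 5356 ± 810 in Q4 (SD, n = 4), with a slope of 105 genes per quartile (exact permutation p = 0.0285, higher in Q1 in 3 of 4 preparations). Without preparation 1, 2 or 3 this slope no longer passed (103.8, 70.8 and 93.6 genes; exact permutation p = 0.0773, 0.191 and 0.0764). Relative sequencing depth was 1.02 ± 0.14 in Q1 and 1.01 ± 0.12 in Q4 (SD, n = 4; exact permutation p = 0.361).

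The brightest cells carried far more transcript of genes tied to stem cell maintenance than the dimmest. Tcl1, a co-activator of the kinase AKT, had the largest difference between Q1 and Q4, with a mean log2(FPKM + 1) of 7.28 ± 0.58 in Q1 and 2.26 ± 1.30 in Q4 (SD, n = 4), a difference of 5.02 (SE 0.43, adjusted p = 1.33e-07). The ERK phosphatase Dusp6 was higher by 4.29 (SE 0.42, adjusted p = 7.33e-07). Etv5, an ETS transcription factor needed for stem cell self-renewal, was higher by 3.74 (SE 0.37, adjusted p = 7.33e-07), and the GDNF co-receptor Gfra1 by 3.44 (SE 0.40, adjusted p = 7.81e-06). The neurofilament gene Nefm, the phosphatase gene Ptpn13, the homeobox gene Hhex, the row Id4e, the basement membrane gene Nid1 and Arhgap26 made up the rest of the 10 largest, at 2.89 to 3.82.

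Fewer genes were lower in bright cells. Upp1, uridine phosphorylase, fell from 5.73 ± 0.87 in Q4 to 2.89 ± 0.81 in Q1 (SD, n = 4), a difference of -2.84 (SE 0.41, adjusted p = 0.000148). Sohlh1, a transcription factor of spermatogonial differentiation, differed by -1.98 (SE 0.35, adjusted p = 0.00132), and Bnip3, a mitophagy receptor, by -1.86 (SE 0.34, adjusted p = 0.00184). Crip2, Ndrg4, the transcriptional co-regulator Cited1, the homeobox gene Rhox10, the galectin gene Lgals2, the small nucleolar RNA host Snhg9 and Asb9 were the other 7, between -2.37 and -1.74. All 20 genes went one way in each of the 4 preparations, as the rule that chose them required.

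In all, 283 genes were higher and 55 lower in Q1 than in Q4 at an adjusted p under 0.05 (limma, 10411 genes tested), and 280 and 55 of them had one sign in every preparation. The split depended on centring. With each mean centred on its median gene, 251 genes passed, and 200 genes were shared. Of the 251, 57.8% were higher, against 83.7% without centring. The median gene lay 0.18 ± 0.17 higher in Q1 (SD, n = 4), but the median of the genes' own differences was 0.10. Centring took that median to -0.08, so it removed more than the typical difference and pushed genes towards lower. The count was 99 without the preparation block, 149, 140 and 149 without preparations 2, 3 and 4, 177 without the expression filter, 173 with the stricter one, 135 with detected genes as a covariate, and 80 (68.8% higher) from the log2 of mean FPKM. The 10 genes named as higher passed in every alternative tested, as did Upp1, Ndrg4, Snhg9 and Bnip3, while each of the other 6 named as lower lost its call in at least 1.

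**Figure D1:**
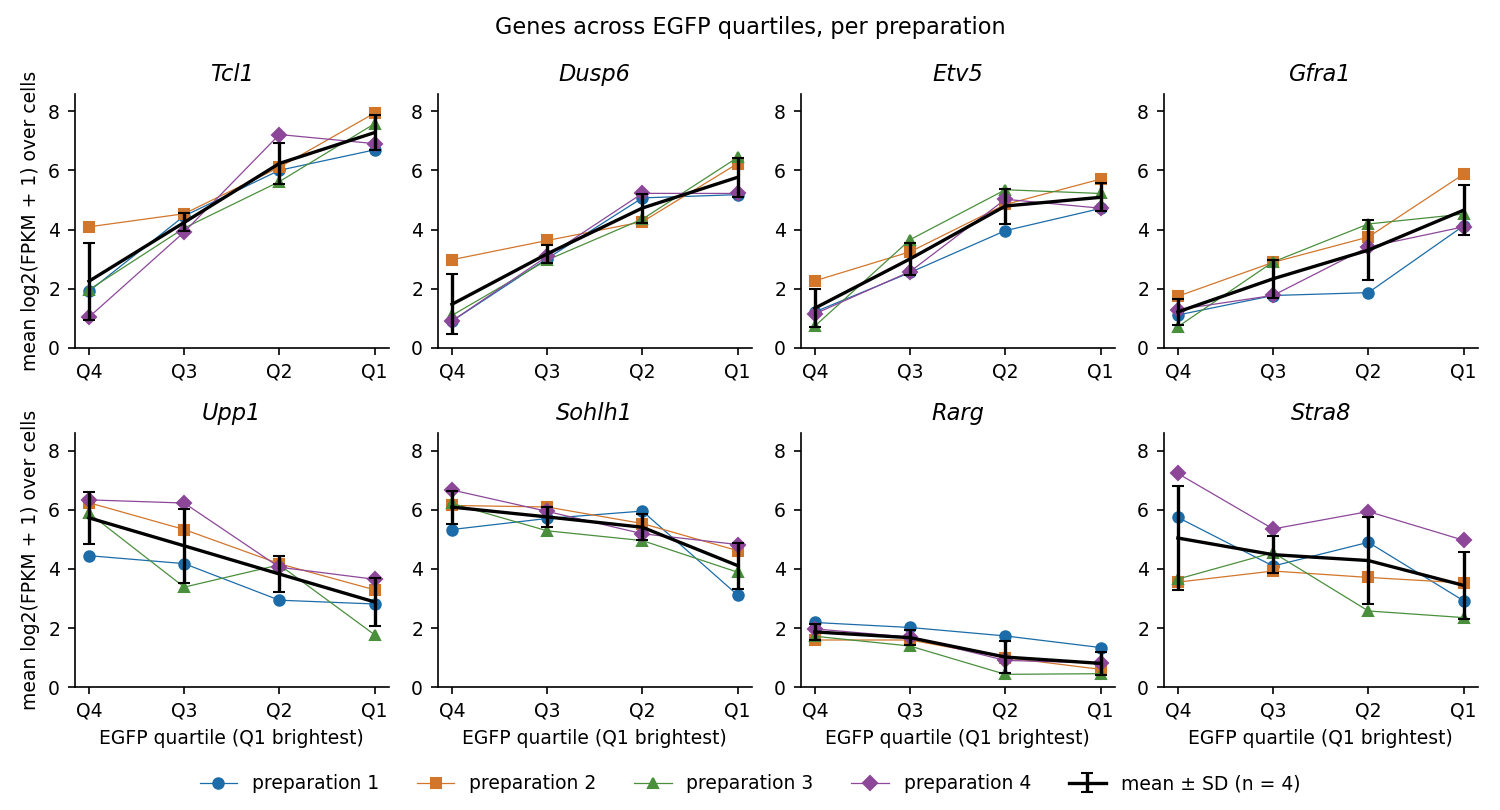
Mean log2(FPKM + 1) over cells (vertical axis) for 8 genes in each EGFP quartile, from Q4, the dimmest, to Q1, the brightest (horizontal axis). Coloured points joined by lines are the 4 preparations, and the black line with bars is their mean ± SD. Tcl1 climbs from 2.26 in Q4 to 7.28 in Q1, and Upp1 drops from 5.73 to 2.89.

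Positions are given for the leading protein-coding genes (GRCm38, GENCODE vM21, gene bounds). Tcl1 lies on chromosome 12 from 105216750 to 105222793, Dusp6 on chromosome 10 from 99263231 to 99267489, Etv5 on chromosome 16 from 22381309 to 22439719, and Gfra1 on chromosome 19 from 58235604 to 58455909. Upp1 lies on chromosome 11 from 9118103 to 9136170 and Sohlh1 on chromosome 2 from 25842995 to 25847248. The values sum all exons of a gene, and reads of antisense neighbours cannot be told apart without strand. Of the 20 genes, exon bases overlap a gene on the opposite strand for Gfra1, Ptpn13, Nid1, Arhgap26 and Bnip3 (predicted genes), Nefm (Nefl), Lgals2 (Cdc42ep1) and Snhg9 (Rps2). Another entry named Arhgap26 shares exon bases on the same strand with genes named by accession codes. No value is given here for Nefl. Cdc42ep1 differed by -0.50 (SE 0.21, adjusted p = 0.222) and Rps2 by -0.43 (SE 0.31, adjusted p = 0.532).

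Among the panel of spermatogonial markers, the stem cell genes Ret (difference 2.02, SE 0.36, adjusted p = 0.00143) and Eomes (2.43, SE 0.33, adjusted p = 7.14e-05) were higher in Q1 beside Gfra1 and Etv5. Cd9, which was also part of the sort, was higher by 1.26 (SE 0.31, adjusted p = 0.0204). The retinoic acid receptor Rarg was lower by -1.06 (SE 0.27, adjusted p = 0.0237), and Stra8, a retinoic acid target of differentiating cells, by -1.60 (SE 0.44, adjusted p = 0.0428). The differences of Bcl6b (0.90), Zbtb16 (0.83), Mki67 (0.52), Nanos2 (0.46), Sall4 (0.41), Ddx4 (0.27), Neurog3 (-0.58), Sox3 (-0.70), Nanos3 (-1.09) and Kit (-1.32) did not pass (adjusted p from 0.0790 to 0.641). Dmrtb1 stood below the expression filter. Stra8 lost its call in 9 of 14 alternatives, Rarg in 7 of 13, Cd9 in 5 of 14, and Ret and Sohlh1 in 1 each. Kit passed with detected genes as a covariate (-2.38, adjusted p = 0.00535) and after median centring (-1.50, adjusted p = 0.0475). Neurog3 passed only after centring (-0.76, adjusted p = 0.0167), which itself pushes genes towards lower.

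The stem cell associated list rose as a group in bright cells. Of its 15 tested members 10 were higher and 0 lower in Q1 (12 and 0 adjusted over the list alone), led by Etv5, Gfra1, Eomes and the forkhead gene Foxc2 (2.32, SE 0.35), and the list passed camera (adjusted p = 3.82e-14). The GDNF and FGF responsive list, which shares Etv5, Bcl6b and Lhx1 with it and Ccnd2 with the differentiating list, had 6 of 12 members higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 2.59e-13). Here the feedback inhibitors of receptor signalling Dusp6, Spry4 (2.42, SE 0.33) and Spry2 (2.25, SE 0.33) stood beside Etv5. Of the surface proteins used for sorting, which share Gfra1, Ret, Mcam and Tspan8 with the stem cell list, 5 of 12 were higher and 0 lower (7 and 1 adjusted over the list alone; camera adjusted p = 1.51e-06), among them Mcam (2.17, SE 0.34) and Tspan8 (2.00, SE 0.40), beside Cd9. The BMP and TGF-beta targets Id3 (1.79, SE 0.43) and Smad6 (1.07, SE 0.25) were the 2 of 5 members that passed (4 and 0 adjusted over the list alone; camera adjusted p = 0.00687). With an estimated correlation these 4 lists had adjusted p of 0.00869, 0.0116, 0.00869 and 0.0371. That call held for the stem cell list in each of 13 alternatives. It was lost for the GDNF and FGF list without preparation 1 (0.0561), for the surface proteins without the block (0.121), and for the BMP and TGF-beta targets in 6 of 12, among them each preparation left out (0.0597, 0.0815, 0.115 and 0.192) and median centring (0.0634). Among their members, Smad6 lost its call in 6 of 13 alternatives, Id3 in 5 of 13 and Tspan8 in 3 of 14.

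Fos was the 1 of 13 immediate early and dissociation stress genes that passed, at 2.24 (SE 0.44, adjusted p = 0.00405), with 5 higher and 0 lower adjusted over the list alone, and it lost its call in 4 of 14 alternatives. Zfp36 differed by 1.31 (adjusted p = 0.0553), Dusp1 by 1.44 (adjusted p = 0.0585) and Ier2 by 0.64 (adjusted p = 0.155). The list passed camera at adjusted p = 0.0240 and lost its call at adjusted p = 0.324 with an estimated correlation. With the preset one it lost its call without preparation 3 (adjusted p = 0.115) and with the stricter filter (adjusted p = 0.119).

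The differentiating, retinoic acid and progenitor lists were lower in bright cells. The differentiating spermatogonia list was lower in Q1 (camera adjusted p = 0.000197) with 3 of 10 members lower, Sohlh1, Stra8 and the retinoic acid binding protein gene Crabp1 (-1.72, SE 0.33), and 1 higher, the D-type cyclin Ccnd2 (1.72, SE 0.33). Adjusted over the list alone, 5 were lower and 1 higher. The retinoic acid pathway list, which shares Stra8 and Crabp1 with it, had 4 of 11 members lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 2.46e-05), with Rarg among the lower ones. In the list of undifferentiated and progenitor spermatogonia (camera adjusted p = 0.000419, lower) Upp1, the ubiquitin hydrolase gene Uchl1 (-0.77, SE 0.16) and Rarg were lower and Glis3 (1.41, SE 0.34) was higher, of 16 tested. Adjusted over the list alone, 4 were lower and 1 higher. With an estimated correlation these 3 lists had adjusted p of 0.0181, 0.0192 and 0.0192. That call was lost for the differentiating list in 3 of 13 alternatives, among them without preparations 1 and 2 (0.0561 and 0.0630), and for the retinoic acid list in 3 of 12, among them without preparations 1 and 3 (0.0818 and 0.0870). It was lost for the progenitor list in 7 of 13, among them without preparations 1, 2 and 3 (0.0561, 0.103 and 0.0876). With the preset correlation the progenitor list lost its call with detected genes as a covariate (adjusted p = 0.0501). Glis3 lost its call in 7 of 14 alternatives, Crabp1 and Ccnd2 in 2 each and Uchl1 in 1.

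Meiotic prophase genes were lower as a list (camera adjusted p = 0.00130), but not with an estimated correlation (adjusted p = 0.113), with Sycp3 of the synaptonemal complex the 1 of 16 members that passed (-0.76, SE 0.21, adjusted p = 0.0377; 1 lower and 0 higher adjusted over the list alone). The call of Sycp3 was lost in 7 of 14 alternatives. The piRNA pathway list had 0 of 15 members past the threshold (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0138, lower), and the ribosomal protein list 0 of 30 (0 and 0 adjusted over the list alone; camera adjusted p = 0.0138, lower, median difference -0.09). With an estimated correlation the latter 2 lost their calls as well, at adjusted p of 0.134 and 0.548. With the preset one the piRNA list lost its call without preparation 4 and the ribosomal list without preparations 2 and 3 (adjusted p = 0.0776, 0.422 and 0.357). The ribosomal list turned to higher with detected genes as a covariate (adjusted p = 0.782).

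**Figure D2:**
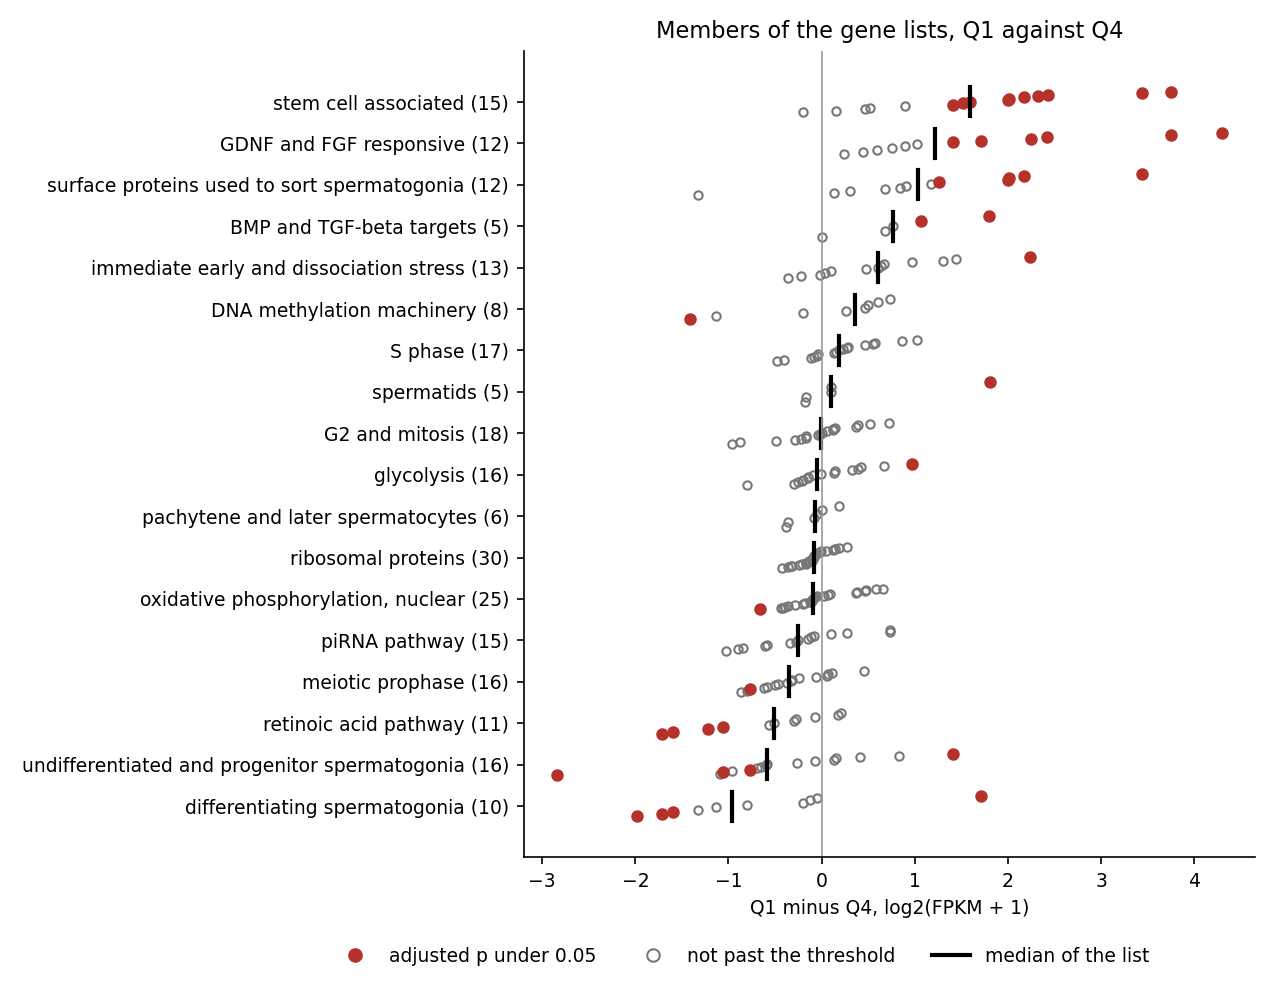
Difference between Q1 and Q4 in log2(FPKM + 1) (horizontal axis) for each tested member of 18 gene lists (vertical axis, number of tested members in brackets). Filled red points have an adjusted p under 0.05, open points do not, and black bars mark list medians. The stem cell associated list has the highest median, 1.59, and the differentiating list the lowest, -0.96.

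Neither cell cycle list passed between Q1 and Q4 or in the trend. None of 17 S phase genes passed (0 higher and 0 lower), with Mcm4 at 1.03 (adjusted p = 0.0944), nor any of 18 genes of G2 and mitosis, with Aurka at -0.97 (adjusted p = 0.160). Their camera tests gave adjusted p of 0.565 and 0.176. The latter passed as lower with detected genes as a covariate and without preparation 3 (adjusted p = 0.00632 and 0.0265), and both calls were lost with an estimated correlation (adjusted p = 0.434 and 0.593). Of 25 nuclear genes of oxidative phosphorylation 1 was lower, the complex I subunit Ndufa2 (-0.66, SE 0.16; list adjusted p = 0.120), of 16 glycolysis genes 1 was higher, the pyruvate kinase gene Pkm (0.97, SE 0.27; list adjusted p = 0.711), and of 8 genes of the DNA methylation machinery 1 was lower, the dioxygenase gene Tet3 (-1.41, SE 0.30; list adjusted p = 0.641). Pkm lost its call in 11 of 14 alternatives, Ndufa2 in 6 of 14 and Tet3 in 4 of 13. The median of the methylation list was 0.36, its mean -0.02 and its camera direction lower. The glycolysis list had a median of -0.05, a mean of 0.06 and a camera direction of lower. Adjusted over the list alone, the counts were 0 for both cell cycle lists, 1 lower for oxidative phosphorylation, 1 higher for glycolysis and 2 lower for methylation.

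Few cells matched the list of another cell type. Of 300 cells, at 5 FPKM or more, 9 carried macrophage or leukocyte transcripts (1 in Q1, 3 in Q2, 2 in Q3 and 3 in Q4; exact permutation p = 0.257), 7 those of pachytene spermatocytes (exact permutation p = 0.793) and 1 those of peritubular myoid cells. At 1 FPKM or more 44 cells matched the pachytene list. At 5 FPKM or more none matched Sertoli, Leydig, endothelial, erythroid or spermatid lists, which allows a share of up to 1%, while at 1 FPKM or more 1 cell matched the endothelial and 2 the spermatid list. The meiotic prophase list stood at the required level in 268 cells and so, by a choice made after the values were seen, did not count as another cell type. Lists of spermatids (1 of 5 tested members higher, Tnp1, also 1 adjusted over the list alone) and pachytene spermatocytes (0 of 6, also 0 adjusted over the list alone) had camera adjusted p of 0.763 and 0.248. Tnp1, a spermatid nuclear transition protein, was higher in Q1 by 1.81 (SE 0.42, adjusted p = 0.0138) and stood at 1 FPKM or more in 51% of cells. It lost its call in 6 of 14 alternatives. Of single tested markers, Star of Leydig cells (0.17), Flt1 of endothelial cells (0.52), Lyz2 (-0.32) and Cd68 (-0.17) of macrophages did not pass (adjusted p from 0.280 to 0.840).

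Many genes rose or fell along the quartiles. In the trend test 393 genes rose and 77 fell towards brighter EGFP (limma, adjusted p under 0.05), and 384 and 76 of them had one sign in every preparation. Tcl1 gained 1.71 per quartile (SE 0.14, adjusted p = 2.01e-08) and Dusp6 1.44 (SE 0.13, adjusted p = 1.06e-07). No test compared the steps between neighbouring quartiles, and Eomes stood at 2.62, 1.49, 0.36 and 0.19 from Q1 to Q4. Beyond the genes already named, the largest slopes belonged to the peroxisomal protease gene Lonp2 (0.96, SE 0.11), Tagln2 (0.94, SE 0.11) and Dpysl2 (0.91, SE 0.12). The immediate early transcription factor Egr2 (0.88, SE 0.12) and Rasgrp2 (0.87, SE 0.12) came next. Pla2g1b (-0.57), Lonrf3 (-0.56), Crabp1 (-0.55), Cyba (-0.55) and the interferon-induced Oasl2 (-0.54) had the steepest further falls. The 5 rising genes passed in each alternative, while of the 5 falling ones Crabp1 alone did so. The same 11 lists passed camera in the same directions as for Q1 against Q4, and 4 of them, the stress, meiotic, piRNA and ribosomal lists, lost their calls with an estimated correlation (adjusted p of 0.270, 0.0766, 0.0862 and 0.574). Of the other 7 the stem cell and GDNF lists kept that call in each alternative, while the progenitor list lost it in 7 of 13, the BMP and TGF-beta targets in 4 of 12, the differentiating list in 2 of 13, the retinoic acid list in 2 of 12 and the surface proteins in 1 of 13. Median centring gave 401 genes, 54.4% of them rising, against 83.6% without centring. It took the median slope over all genes from 0.034 to -0.025, so it pushed genes towards falling. Detected genes as a covariate gave 197 with 72.1% rising. Without the block 177 passed, without the filter 274, with the stricter filter 232, from the log2 of mean FPKM 113, and without preparations 2, 3 and 4 246, 183 and 217.

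**Figure D3:**
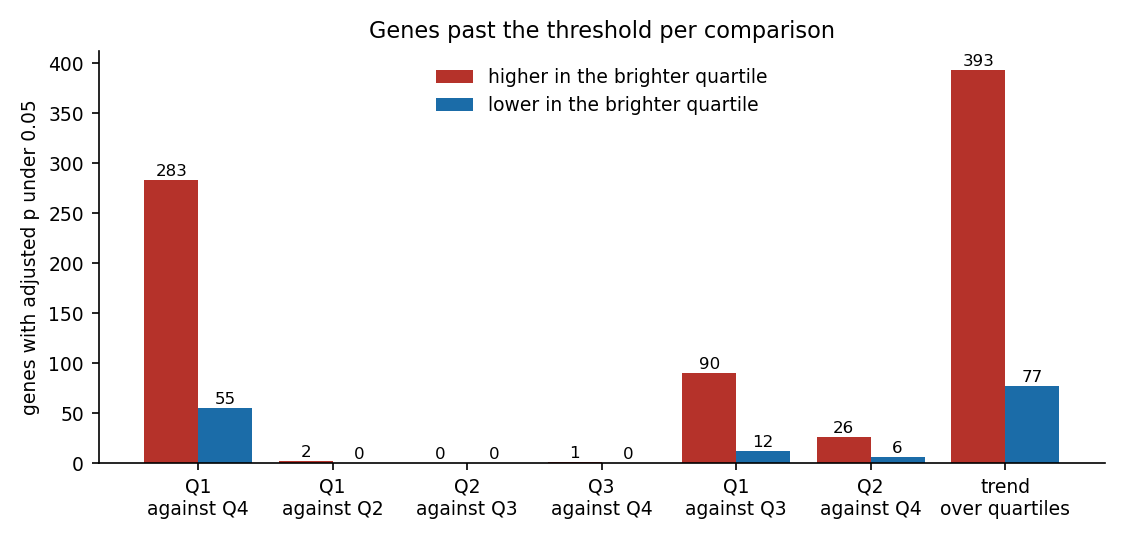
Number of genes with an adjusted p under 0.05 (vertical axis) in each of the 7 comparisons (horizontal axis), red for genes higher and blue for genes lower in the brighter quartile. Q1 against Q4 has 283 and 55, the trend 393 and 77, and neighbouring quartiles at most 2.

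More genes passed between quartiles that lie further apart. Against Q3, Q1 had 90 genes higher and 12 lower, with Nefm (3.37, SE 0.40), Tcl1 (3.04, SE 0.43) and Id4e (2.81, SE 0.33) highest and Ndrg4 (-2.36, SE 0.35), Upp1 (-1.90, SE 0.41) and Rhox10 (-1.71, SE 0.39) lowest. Against Q4, Q2 had 26 higher and 6 lower, with Tcl1 (3.98, SE 0.43), Etv5 (3.45, SE 0.37) and Dusp6 (3.25, SE 0.42) highest and Bnip3 (-1.91, SE 0.34), Upp1 (-1.90, SE 0.41) and the mitotic kinase gene Aurka (-1.63, SE 0.36) lowest. After median centring 74.7% of 75 genes were higher for Q1 against Q3, against 88.2% of the main 102. For Q2 against Q4 it was 57.1% of 28, against 81.2% of 32. Centring took the median difference over all genes from 0.098 to -0.048 and from 0.048 to -0.041, which favours lower calls. Without the block 33 and 5 genes passed.

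Few genes passed between neighbouring quartiles. This does not show that neighbours were alike, since the test with planted level changes found 28% of 4-fold ones even for Q1 against Q4. Id4e (2.00, SE 0.33) and the endosomal GTPase gene Rab4a (1.58, SE 0.26) were the 2 genes higher in Q1 than in Q2 (adjusted p = 0.0141 for both, higher in 4 of 4 preparations). What Id4e covers is not stated, so its difference may follow from how the quartiles were made. The heparan sulfate proteoglycan gene Sdc4 was the 1 gene higher in Q3 than in Q4, by 0.97 (SE 0.15, adjusted p = 0.00757, 4 of 4 preparations), and was listed at 10.7 in Q1 and 9.78 in Q4. Between Q2 and Q3 limma called 0 genes. Of 10411 tested, 767 had an unadjusted p under 0.05, where chance alone puts a share of about 0.05. Without the block or the filter 0 genes passed in any of the 3 comparisons of neighbours.

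Counted as shares of cells with at least 1 FPKM, Etv5, Gfra1, Ret and Eomes were found in far more bright than dim cells. Etv5 was detected in 94.8% ± 4.3 of Q1 cells and 32.3% ± 15.5 of Q4 cells, Gfra1 in 81.9% ± 13.5 and 28.5% ± 8.4, Ret in 79.5% ± 2.4 and 33.5% ± 8.5, and Eomes in 57.4% ± 16.3 and 6.38% ± 7.59 (SD, n = 4). Bcl6b went from 41.7% ± 17.6 to 18.8% ± 9.6, and Nanos2 from 18.2% ± 8.3 to 7.21% ± 5.93 (SD, n = 4), and Nanos2 did not pass (exact permutation adjusted p = 0.114). Rarg went from 30.7% ± 8.3 in Q1 to 61.1% ± 8.7 in Q4, and Kit, the receptor of differentiating spermatogonia, from 21.3% ± 8.2 to 47.2% ± 26.9. By the exact permutation of quartile labels, 9 of 19 panel genes passed after adjustment over the panel, namely Gfra1, Ret, Etv5, Eomes and Bcl6b rising and Rarg, Sox3, Kit and Sohlh1 falling with brightness (adjusted p from 0.000344 to 0.0424). Stra8 was detected in 66.4% ± 14.3 of Q1 and 69% ± 10.5 of Q4 cells (SD, n = 4; exact permutation adjusted p = 0.875), although its mean level was lower in Q1. The count fell to 5 without preparation 2 or 3.

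Cells with Gfra1 and without Kit made up 65.8% ± 11 of Q1 and 17.2% ± 12.6 of Q4 (SD, n = 4; exact permutation adjusted p = 0.00422), 131 cells in all. Cells with Kit and without Gfra1 went the opposite way, 5.24% ± 4.33 against 35.9% ± 23 (SD, n = 4; exact permutation adjusted p = 0.00709), 50 cells. In Q4 they made up 68.4% of the cells of preparation 4 and 15% to 33.3% of those of the others, and without it the slope went from -9.23 to -5.89 points per quartile (exact permutation adjusted p = 0.0407). Cells with neither were 12.9% ± 12 and 35.6% ± 21.1 (SD, n = 4; exact permutation adjusted p = 0.0470), 76 cells, and this call was lost without preparation 1, 2 or 3 (adjusted p of 0.0804, 0.253 and 0.230). Cells with both, 43 in all, made up 16% ± 6.9 of Q1 and 11.3% ± 4.6 of Q4 (SD, n = 4; exact permutation adjusted p = 0.564).

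**Figure D4:**
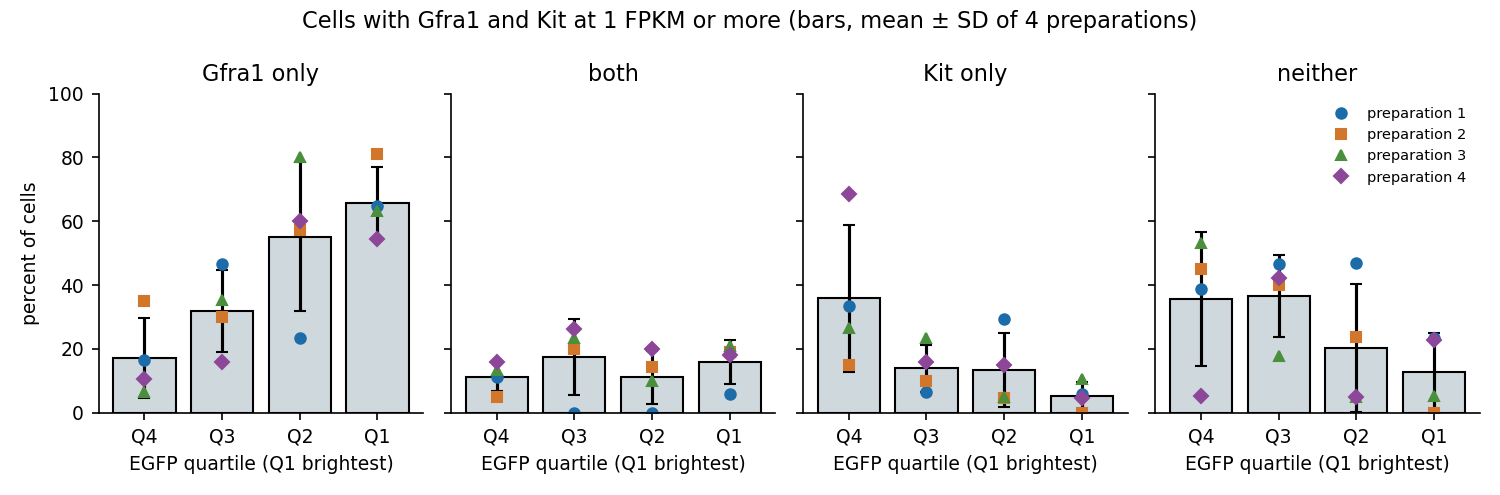
Percent of cells (vertical axis) with Gfra1 only, both genes, Kit only or neither at 1 FPKM or more in each EGFP quartile (horizontal axis, Q4 dimmest). Bars and error bars are the mean ± SD of 4 preparations and points are the preparations. Gfra1-only cells make up 17.2% of Q4 and 65.8% of Q1.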

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

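The tests weighed here for Tnp1, for the surplus of higher genes, for other splits of the samples and other assignments of cells and, for the leukocyte transcripts, the Dazl test were chosen after the results were seen, and the Ddx4 and detected-gene tests before, though the latter was made stricter afterwards.

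In 10 of 192 groups of 4 preparations 1 value lay far from the other 3, where chance gives about 1 in 20, or 9.6. Preparation 2 stood high for Dusp6 in Q4 (mean log2 2.98, others 0.909 to 1.10) and for Id4e in Q1 (4.84, others 3.51 to 3.62) and low for Lonrf3 in Q4 (4.38, others 5.64 to 5.81). Preparation 1 stood low for Ptpn13 in Q1 (4.18, others 4.82 to 4.94), Upp1 in Q2 (2.94, others 4.06 to 4.18) and Cited1 in Q3 (1.28, others 1.75 to 1.84). It was also low for genes per cell in Q1 (4652, others 5894 to 6108) and for total FPKM in Q4 (479498, others 490940 to 492598). Preparation 4 stood high for Nid1 in Q3 (1.96, others 0.781 to 0.876) and Ndrg4 in Q4 (6.53, others 4.80 to 4.96).

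More genes were higher than lower in Q1 against Q4. Deeper sequencing of bright cells is argued against, since relative depth was 1.67% higher in Q1 and higher in 2 of 4 preparations. A larger number of detected genes as the whole cause is argued against as well, because with that number as a covariate 135 genes passed, 121 of them among the 338, and 81.5% of the 135 were higher in Q1. With the same covariate the median difference over all genes was -0.0135, so no general upward shift was left, and still 81.5% were higher. For these 135 genes this argues against a general shift of log values between quartiles as the whole cause. For the rest of the 338 it stays open. Centring on the median gene, after which 57.8% were higher, cannot decide it, because it itself sets the balance of higher and lower genes. It took the median difference from 0.10 to -0.08.

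Tnp1, a spermatid gene, was higher in Q1. Free RNA or remnants of spermatids stay open. The Tnp1 difference exceeded the median of Prm1, Prm2 and Tnp2, which spermatids also hold in abundance, by 1.97. However, Prm1, Prm2 and Tnp2 were detected in 22.3%, 26.3% and 11% of cells, and a difference on this scale understates the change of such low genes. Mean FPKM was 50.4 for Tnp1 against 3.02, 1.90 and 1.14 for Prm1, Prm2 and Tnp2. These means argue only against a source that holds all of them in like amounts. Reads of the antisense gene 1700027A15Rik, which shares 9.15% of the Tnp1 exon bases, are argued against by its mean FPKM of 0.167% of that of Tnp1. Transcription of Tnp1 in bright spermatogonia is another hypothesis, which was not tested. The call was lost in 6 alternatives, including those without preparations 1, 3 and 4 (differences of 1.64 to 1.67).

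The 9 cells with leukocyte transcripts, 6 of them in preparation 3, held a median of 1326 FPKM of Lyz2, 315 of C1qb and 257 of C1qc, each at a median of 0 in the other 291 cells, although the sort required ID4-EGFP. Leukocytes in place of spermatogonia could not be judged from Ddx4, which stood above 50% of the other cells' median in 3 of them and under 10% in 1. The germ cell gene Dazl argues against it, at over 50% of that median in 9 of 9 and 65.6% in the lowest. A spermatogonium and a leukocyte in 1 capture site cannot be told apart from a spermatogonium that took up leukocyte RNA, since the median excess of 190 detected genes over cells of the same preparation lay within random draws of 9 cells (one-sided permutation p = 0.302). No biological explanation was tested.

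When cells were reassigned to quartiles at random within preparations, which keeps the pairing, 1 of 100 assignments, the real one, reached the count for Q1 against Q4 (real 338, highest other 0), Q1 against Q3 (102, 0), Q2 against Q4 (32, 1), Q1 against Q2 (2, 1) and the trend (470, 1). Chance assignment is argued against for these, although the 2 genes of Q1 against Q2 depend on the settings and include Id4e, which may follow brightness by definition. For Q3 against Q4 it was 4 of 100 (real 1, highest other 1) and for Q2 against Q3 100 of 100 (real 0, highest other 1).

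Of the 35 splits of the 8 means of a pair of quartiles, 8 part every preparation as the real one does, too few for a share under 0.05. Among these the highest other count was 0, except 1 for Q2 against Q3 and Q3 against Q4. The remaining splits leave both means of at least 1 preparation on one side. Over all 35, as many genes came from 1 split, the real one, for Q1 against Q4 (highest other 0), Q1 against Q2 (1), Q1 against Q3 (1) and Q2 against Q4 (0), from 2 for Q3 against Q4 (1) and from 35 for Q2 against Q3 (1). For the trend, 1 of 100 assignments of whole means within preparations, the real one, gave 470 genes (highest other 0), which argues against chance there. For Q3 against Q4 chance stays open, since the 2 tests differ, with 2 of 35 splits and 4 of 100 assignments of cells reaching the real count. A real count of 0, as for Q2 against Q3, is reached by every split and says nothing about chance.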

How the results depend on the processing

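Median centring was chosen after the data were seen, and the other settings before. For Q1 against Q4 the 338 calls were 177 with no filter, 173 with the filter of 150 cells, 80 from the log2 of mean FPKM, 135 with detected genes as a covariate, and 140 to 273 with 1 preparation left out. The trend's 470 were 274, 232, 113, 197, and 183 to 346. Q1 against Q3 (102) gave 46, 41, 7, 57, and 31 to 88. Q2 against Q4 (32) gave 7 with no filter, 6 from the log2 of mean FPKM, and 4 to 19 with 1 preparation left out. Q1 against Q2 (2) gave 0 with no filter, the stricter filter, the log2 of mean FPKM or the compared quartiles only, 1 with the covariate, and 0 to 1 with 1 preparation left out. Q3 against Q4 (1) gave 2 with a pseudocount of 0.1 or without cells of other types, 0 with no filter, the log2 of mean FPKM or median centring, and 0 to 2 with 1 preparation left out. Q2 against Q3 (0) gave 0 to 1 with 1 preparation left out. Settings not named in this part kept the counts of genes within 1.5 times. More genes tested without the filter and fewer samples with a preparation left out lower the power by construction, and for the other settings the cause was not tested.

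Without the preparation block the pairing is ignored, and the counts were 99 for Q1 against Q4, 0 for Q1 against Q2, 0 for Q3 against Q4, 33 for Q1 against Q3, 5 for Q2 against Q4 and 177 for the trend. All 99 and 177 were among the main calls.

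Of 11 lists past the threshold, 7 passed with an estimated correlation for Q1 against Q4 and for the trend, of which 1 and 2 did so in every alternative. With the preset correlation, leaving out 1 preparation gave 10 to 11 lists and 9 to 11 lists. The 9 panel genes by share of cells became 5 to 6. The slope of cells with neither Gfra1 nor Kit, -8.46 points per quartile, ran from -11.8 to -6.05, and that of detected genes per cell, 105, from 70.8 to 152, with calls lost without preparations 1, 2 and 3. The slope of cells with Kit and without Gfra1, -9.23, ran from -10.6 to -5.89 and kept its call. Cells with markers of another type were 17 at 5 FPKM and 55 at 1 FPKM. No cell held under 2000 genes, so the setting without such cells was not run.

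Sign changes concerned genes that were not called. From the log2 of mean FPKM, Hspa2 was at -0.43, Piwil1 at 0.11 and Prm2 at 0.000253. With the covariate, Nanos3 was at 0.0621, Ddx4 at -0.28, Mki67 at -0.28, Tnp2 at 0.11 and Bub1 at -0.0833. Cd68 was at 0.00465 without cells of other types, and after median centring Prm1 was at -0.0722 and Star at -0.0109. With a preparation left out, Hspa2 ran from -0.22 to 0.48, Piwil1 from -0.21 to 0.0780, Prm1 from -0.0388 to 0.27, Prm2 from -0.27 to 0.0165 and Cd68 from -0.57 to 0.0863. Absolute depth is unknown, and the test with planted level changes found 28% of 4-fold ones, which limits the smaller differences.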

Other observations

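All tests of this part were chosen after the results on called genes were seen, and the criterion for the first hypothesis was changed 2 times after its own values were seen.

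The share of cells with Stra8 differed more between the cell classes than between Q1 and Q4, where it differed by -2.57 points. The level of Stra8 in detecting cells differed between Q1 and Q4 as well, by -2.11 on the log2 scale. Stra8 was detected in 92.3% ± 7.0 of cells with Kit and without Gfra1 and in 91.7% ± 11.8 of cells with both, but in 57.8% ± 14.6 of cells with Gfra1 only and 50.9% ± 13.5 of cells with neither (SD, n = 4). In cells that detected it, its mean log2 FPKM was 7.90 ± 1.04 with Kit only, 7.68 ± 0.41 with both, 5.27 ± 0.67 with Gfra1 only and 4.76 ± 0.57 with neither (SD, n = 4), taken per preparation. No test was run on these classes, and a preparation held as few as 3 cells with both.

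A first hypothesis was that bright and dim cells differ in how many cells express a gene and not in the level per cell. It was tested in each preparation on genes called from the other 3, 117 to 230 of them higher in Q1. In the preparation left out, the share of detecting cells differed by a median of 24.8 ± 7.5 percentage points, and the level in detecting cells by 0.56 ± 0.13 on the log2 scale (SD, n = 4). For genes not called, these medians were 2.54 ± 2.18 points and -0.0300 ± 0.0464. In all 4 preparations the level difference of the called genes exceeded that of the others, on average by 0.59 (SE 0.06). This argues against a change alone in the share of cells at 1 FPKM or more, for the 93 to 167 genes with enough detecting cells for a level. For the rest, whose shares differed by a median of 37.1 ± 13.3 points, it stays open, since they had no level to compare. A cell with only a trace of a gene can count as detecting. Lyz2, for one, was detected in 9.28% of the 291 cells other than those with leukocyte transcripts. Where fewer cells express a gene, such traces would lower the level as well. A change alone in the share of cells that express a gene therefore stays open. The result for the share at 1 FPKM or more rests on the latest criterion, an excess over genes not called by more than 3 SE and in all 4 preparations. Under the one before it, a level difference above 0.5 by more than its SE of 0.07, the hypothesis stayed open for all of these genes.

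A second hypothesis was that the difference comes only from there being more Gfra1-detecting cells in Q1. In the preparation left out, the median difference of genes called higher from the other 3 was 1.37 ± 0.34 among Gfra1-detecting cells and 1.45 ± 0.40 among all cells (SD, n = 4), on average 96% (SE 5.7). Genes not called had a median of 0.20 ± 0.14 in Gfra1-detecting cells. This argues against the share of such cells as the whole cause for the higher genes. For genes called lower the medians were -0.71 ± 0.53 and -1.04 ± 0.41, and -0.19 in preparation 1. A preparation held as few as 3 Gfra1-detecting cells in Q4, and Gfra1 itself differed among the Gfra1-detecting cells by 1.47 ± 0.52. Cells with only a trace of Gfra1 can count as detecting here too, so the share of cells that express it stays open as a cause.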
